A study of Rattus norvegicus with 48 samples.

How the data were processed

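Polyadenylated RNA from the liver and the testis of adult male Sprague-Dawley rats was sequenced after 14 days of daily gavage with corn oil or with myclobutanil, and 48 libraries were used here. Per the labels' protocols, total RNA was extracted with a column kit with DNase digestion and made into libraries with a stranded mRNA kit. Per the submitters' processing notes, the tools were CASAVA 1.8, HISAT2 and HTSeq 0.6.1; the genome build and the strand setting of the counting are not given in the sources used here. The deposited files hold whole-number read counts per Ensembl rat gene, 1 file per library and not normalised. Each file also has 5 lines that belong to no gene, for reads outside genes, ambiguous reads, reads of low mapping quality, reads not aligned and reads without a unique alignment. Those lines held 39.8% to 46.1% of all reads in liver and 34.9% to 36.9% in testis, and they were left out of library sizes and tests. Reads with several alignments were therefore not counted for any gene, and genes with near-identical copies are measured with less certainty. Library totals over genes were 31.8 to 49.1 M reads in liver and 30.9 to 49.2 M in testis.

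Groups were taken from the sample titles and the dose label, with 6 libraries in each of 8 groups. Testis libraries 2407 and 2408 are titled vehicle with a dose of 0, while another label of theirs names myclobutanil. They were kept as vehicle, and leaving both out was 1 of the alternatives. Each number in the titles, 2403 to 2426, occurs once in liver and once in testis. The labels do not say that a number is an animal, so p-values measure the spread between libraries of a group. Within groups, pairs of libraries differed by far more than sampling noise, with a chi-square per degree of freedom of 27.6 to 88.4 over 60 pairs in liver and of 6.59 to 36.6 over 60 pairs in testis. Log2 CPM over 14733 genes correlated at 0.986 to 0.994 between liver libraries, at 0.989 to 0.994 between testis libraries and at -0.00672 to 0.0421 between the tissues.

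The files pair no ID with a gene name, and 0 of the 32545 IDs matched a symbol through the reference table of 47357 genes. The 30 gene lists and the tissue markers fixed before the data were examined, with their camera and fry tests, could therefore not be applied. The rule for named genes asked for a symbol, an adjusted p under 0.05, a mean CPM of at least 1 and every treated library on the same side of the vehicle mean, ranked by fold change. Without symbols, genes are described by number, and 4 are given by their ID. These are the genes called in liver at 30 mg/kg and the gene with the lowest fold change at 400 mg/kg in each tissue under the other parts of the rule; this choice was made after their values were seen. Genes were also grouped by mean CPM, and by their ratio between the tissues in the 30 mg/kg groups with a limit of 8-fold; both groupings were chosen after the names were found missing.

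Differential expression was tested per tissue on all 24 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, estimated dispersions, a robust quasi-likelihood fit with 1 mean per dose group, and 2-sided tests with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. The difference between the tissues in the effect of 400 mg/kg was tested in 1 fit of all 48 libraries. Standard errors of log2 fold changes were taken from the fold change and the F statistic. CPM values are scaled by TMM within a tissue; log2 CPM for correlations, principal components and directions used a prior count of 2. Shares of reads and library totals were compared with exact permutation tests, 2-sided, whose smallest p for 6 against 6 libraries is 0.00216, adjusted over 24 tests. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom 3.58.1 with sample quality weights, no filter or a mean CPM of at least 1, only the 12 libraries compared, a fit that was not robust, a fold change of at least 1.5, each library left out and, across tissues, a block on the title number.

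The steps were tested on simulated counts for the 400 mg/kg comparison of each tissue, with 60 genes changed 1.25-fold, 70 changed 1.5-fold and 70 changed 2-fold. The changed genes had a mean CPM of at least 1, and no difference between sequencing sets was simulated. The shares recovered therefore do not cover genes of lower expression or the effect of the sets. In liver, over 13275 genes, 35%, 85.7% and 92.9% of them were recovered, with 5 false calls. In testis, over 17261 genes, the shares were 56.7%, 84.3% and 95.7%, with 4 false calls. Comparisons with the same vehicle libraries share their chance values. Their overlap was therefore set beside 10 simulations of unchanged groups, their correlation beside 20, and both beside 10 divisions of the vehicle libraries into 3 and 3.

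The libraries fall into 3 sequencing sets that were inferred here from depth and mapping quality, since the labels name no batch. In testis, the share of reads of low mapping quality was 2.72% to 2.84% in 10 libraries, 5 vehicle and 5 at 30 mg/kg, and 2.52% to 2.58% in the other 14. Of these 14, the libraries numbered 2408, 2414, 2415 and 2421, 1 per dose, had 43.1 to 49.2 M reads, against 30.9 to 38.3 M in the other 10, which are 5 at 150 mg/kg and 5 at 400 mg/kg. These are called the first set (10 libraries), the third (4) and the second (10). The liver libraries of the same numbers had 31.8 to 37 M reads in the first set, 38.5 to 41.6 M in the second and 45 to 49.1 M in the third. The comparison of 30 mg/kg with vehicle and that of 400 with 150 mg/kg are balanced over these sets. Those of 150 and 400 mg/kg with vehicle are confounded with them except through 2408 and 2414, so the set was added as a term after the data were examined.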

Results

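Gene expression was measured in liver and testis of adult male Sprague-Dawley rats, 8 to 10 weeks old at the start, after 14 days of daily oral gavage. Rats received corn oil at 4 ml/kg as the vehicle, or myclobutanil, a triazole fungicide, at 30, 150 or 400 mg/kg. Each tissue had 6 libraries per dose, 24 in all. Between 31.8 and 49.1 M reads per liver library and between 30.9 and 49.2 M per testis library were assigned to genes. Mean totals did not differ from vehicle beyond the spread between libraries at any dose in either tissue; the smallest exact permutation p was 0.132, for liver at 150 mg/kg (41.6 ± 2.28 against 37.3 ± 6.04 M reads, SD, n = 6). Depth, and in testis mapping quality, divided the libraries into 3 inferred sequencing sets: the first held 5 vehicle and 5 30 mg/kg libraries, the second 5 150 mg/kg and 5 400 mg/kg libraries, and the third 1 library per dose. In liver, the second set had 38.5 to 41.6 M reads and the first 31.8 to 37 M, so depth partly followed dose. The deeper third-set library in each liver group widened the spread used in the test of mean totals. The files do not pair gene IDs with names, so genes are described as groups and 4 by ID.

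**Figure D1:**
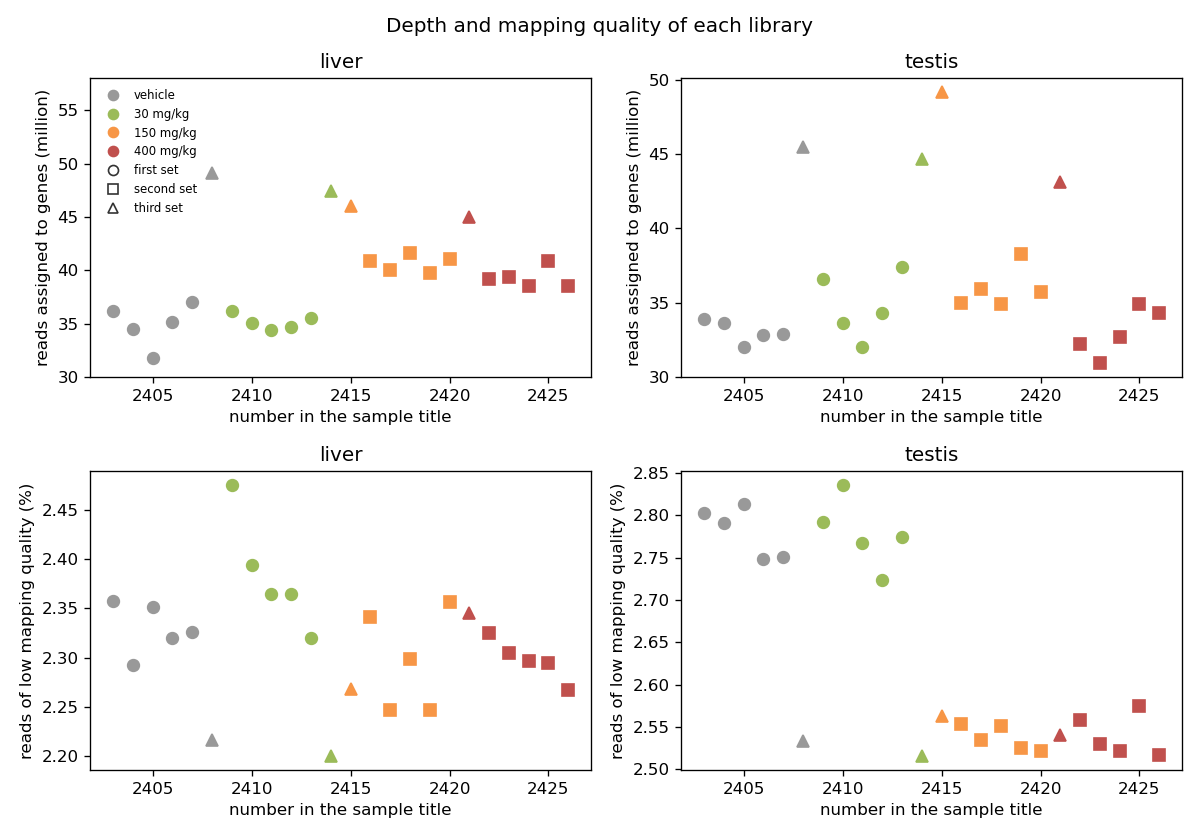
Reads assigned to genes (M) and share of reads of low mapping quality (%) in each library, by the number in its title; colours are doses and symbols are the sequencing sets. In testis the 10 libraries of the first set lie at 2.72% to 2.84% and the other 14 at 2.52% to 2.58%.

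The comparison of 400 mg/kg with vehicle asks which liver genes respond to the highest dose. In liver, 1324 genes rose and 1284 fell at 400 mg/kg, 19.6% of the 13275 tested. Most changes were small: the median was 1.29-fold among genes that rose and 1.34-fold among those that fell. At least 2-fold changes were seen in 141 genes that rose and 222 that fell, and 8-fold changes in 20 and 11. The strongest rise was that of ENSRNOG00000033680, from 4.88 ± 1.76 CPM with vehicle to 2550 ± 906 CPM (SD, n = 6), a log2 fold change of 9.02 (SE 0.50, adjusted p = 2.62e-11). ENSRNOG00000020775 rose from 34.0 ± 12.8 to 1210 ± 472 CPM, by 5.15 on the log2 scale (SE 0.34, adjusted p = 7.62e-10). Among genes that fell, ENSRNOG00000030868 had the lowest fold change under the rule for named genes, at -6.24 (SE 0.94, adjusted p = 8.11e-05). It went from 4.95 ± 3.20 CPM to 0.0619 ± 0.0438 CPM, which rests on 1 to 5 reads per library at 400 mg/kg. The 10 genes that led the rise under that rule, symbols aside, had log2 fold changes of 3.54 to 9.02, and the 10 that led the fall had -6.24 to -2.50.

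The liver response at 400 mg/kg reached genes of every expression level. Of 1110 genes with a mean over 100 CPM, 407 were called, 181 higher and 226 lower. Of 5727 genes at 10 to 100 CPM, 751 rose and 501 fell. Among 1986 genes under 1 CPM, 153 fell and 50 rose. The share of gene reads taken by the 10 most abundant genes was 29.8% ± 1.49 with vehicle and 26.1% ± 0.823 at 400 mg/kg (SD, n = 6, exact permutation p = 0.00216, the smallest possible, adjusted 0.0173 over 24 tests), with every treated library below the vehicle mean. In the third set it was 27.9% in the vehicle library and 26% in the 400 mg/kg library, too few for a test. Over all 13275 genes tested, the 6 and 6 libraries did not overlap for 1062, where chance gives no overlap in a share of 0.00216. With the sequencing set as a term of 2 levels, 936 genes were called, 526 higher and 410 lower, 848 of them also among the 2608; with a term of 3 levels 695 were called, and 834 with a fold change of at least 1.5. The term itself was called for 0 genes by edgeR (840 at an unadjusted p under 0.05).

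**Figure D2:**
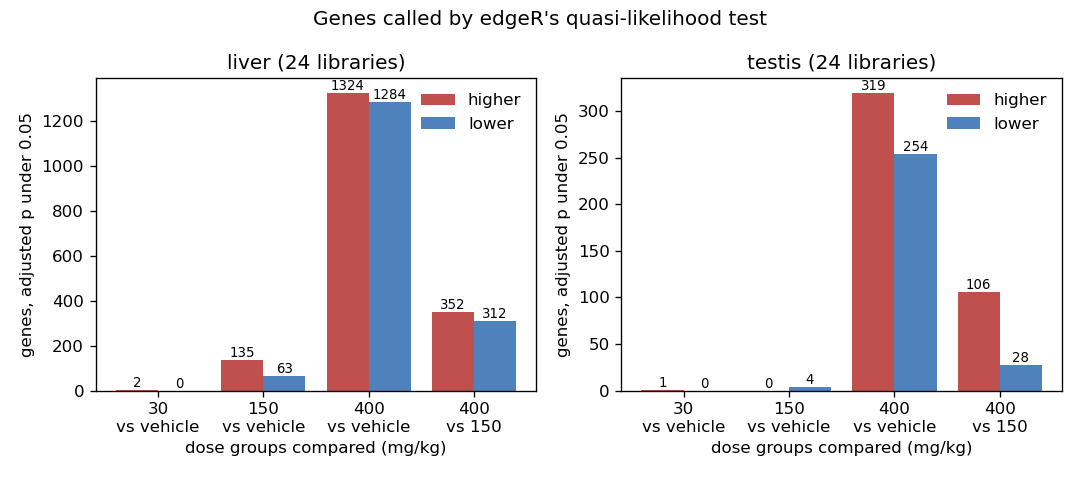
Number of genes called higher (red) and lower (blue) in each comparison of dose groups (mg/kg), for liver and testis. Liver counts rise from 2 at 30 mg/kg to 198 at 150 mg/kg and 2608 at 400 mg/kg, and testis has 573 at 400 mg/kg.

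At 150 mg/kg, 135 liver genes rose and 63 fell against vehicle, with median changes of 1.36-fold and 1.51-fold. ENSRNOG00000033680 was at 950 ± 460 CPM (SD, n = 6; log2 fold change 7.60, SE 0.47, adjusted p = 1.38e-09) and ENSRNOG00000020775 at 470 ± 194 CPM (3.79, SE 0.32, adjusted p = 1.84e-07). ENSRNOG00000030868, at 1.07 ± 1.36 CPM, did not pass the test (-2.20, SE 0.66, adjusted p = 0.0924). Of the 198 genes, 182 were also called at 400 mg/kg in the same direction, 131 higher and 51 lower, and 0 in the other direction. Independent lists would share 13.5 and 6.09; simulated unchanged groups with the same controls shared 0, but with at most 3 and 1 genes called these lists were too short to measure an overlap. When each dose was set against a different 3 of the vehicle libraries, 65 and 1550 genes were called on average and 51 were shared, against 3.88 for independent lists. Both doses differ from vehicle in sequencing set in the same way, and none of these values takes that into account. Leaving out vehicle 2403, 2404 or 2408, or 150 mg/kg 2416, 2418 or 2419, left 104 to 116 genes. The set as a term of 2 levels gave 107 genes, 61 of them among the 198, and of 3 levels 209, 60 of them among the 198; DESeq2 called 494, and 85 changed at least 1.5-fold.

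At 30 mg/kg, the lowest dose, 2 liver genes were called, and both rose. ENSRNOG00000033680 was 15.8-fold higher, at 77.3 ± 32.1 CPM (SD, n = 6; log2 fold change 3.98, SE 0.40, adjusted p = 2.00e-05). ENSRNOG00000020775 was 5.27-fold higher, at 180 ± 65.0 CPM (2.40, SE 0.30, adjusted p = 0.000479). For both genes, all 6 treated libraries lay above all 6 vehicle libraries. No gene was called lower by edgeR, with 696 genes, 5.24% of those tested, at an unadjusted p under 0.05 in either direction; DESeq2 called 16 higher and 3 lower and limma-voom 4 higher. Within the first set, 5 against 5 libraries, 4 genes were called, these 2 included. Leaving out vehicle 2406 gave 4 genes and leaving out 2412 gave 5.

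**Figure D3:**
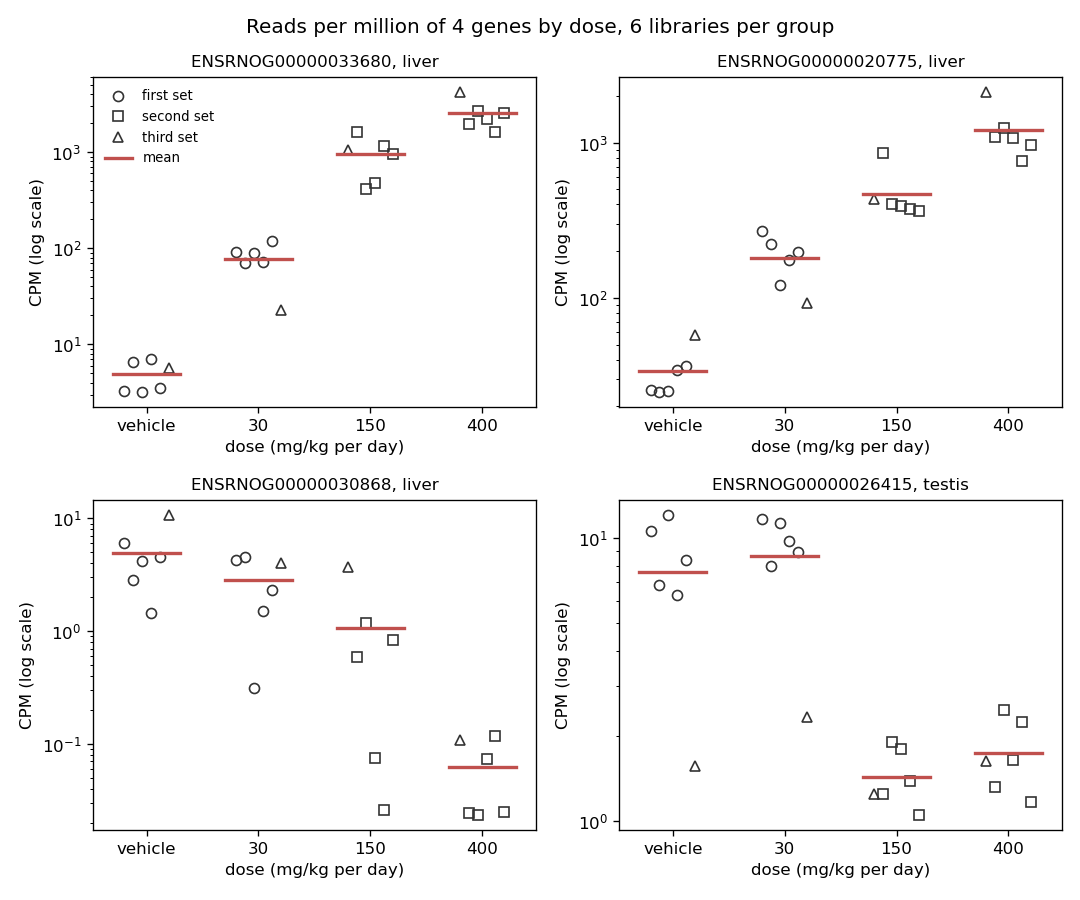
CPM on a log scale of the 4 genes given by ID, by dose (mg/kg per day); each point is a library, symbols are the sequencing sets and bars are group means. The upper panels rise at each dose step in liver, from 4.88 to 2550 CPM and from 34.0 to 1210 CPM; at lower right, the vehicle and 30 mg/kg libraries of the third set lie at 1.56 and 2.34 CPM, with the 150 and 400 mg/kg libraries.

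Between 150 and 400 mg/kg, 352 liver genes were higher and 312 lower at 400 mg/kg. Of these 664, 560 were also called at 400 mg/kg against vehicle in the same direction. Both comparisons use the same 400 mg/kg libraries and share their chance values, which favours such an overlap, and no value for unchanged groups was computed. The genes that led the rise under the rule for named genes went up by 2.26 to 3.59 on the log2 scale, and those that led the fall had -2.48 to -1.80. ENSRNOG00000033680 rose by 1.42 (SE 0.35, adjusted p = 0.0235), ENSRNOG00000020775 by 1.36 (SE 0.29, adjusted p = 0.0105), and ENSRNOG00000030868 fell by 4.03 (SE 1.0, adjusted p = 0.0235). Of the 198 genes called at 150 mg/kg, 50 moved further in the same direction and 3 moved back. The count was 288 with only the 12 libraries compared and 68 within the second set, 5 against 5, 418 without a filter, 145 with a fold change of at least 1.5 and 1035 with DESeq2. It was 436, 398 and 408 without 150 mg/kg 2415, 150 mg/kg 2418 and 400 mg/kg 2423. The call for ENSRNOG00000033680 ended with only the 12 libraries (1.42, adjusted p = 0.0536, against 0.00176 to 0.0261 under the other alternatives) and that for ENSRNOG00000030868 with limma-voom (-2.77, adjusted p = 0.303, against 0.000168 to 0.0236). Alternatives for these calls were RLE size factors, DESeq2, limma-voom, only the 12 libraries and the set as a term of 2 levels. Fits without 1 library are not in these ranges.

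**Figure D4:**
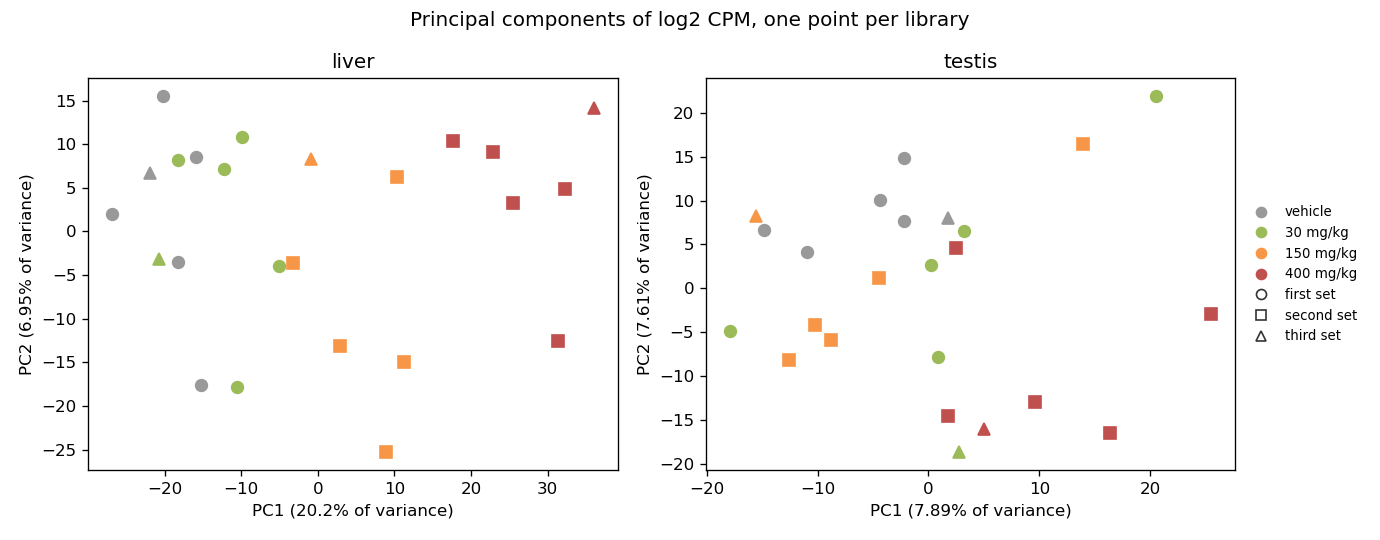
Libraries on the first 2 principal components of log2 CPM in each tissue; colours are doses and symbols are the sequencing sets. In liver the 400 mg/kg libraries lie at 17.7 to 36 on the first component and the vehicle libraries at -26.8 to -15.2; in testis the vehicle libraries lie at -14.8 to 1.73, those at 400 mg/kg at 1.8 to 25.5, and the other doses overlap both.

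In testis at 400 mg/kg, 319 genes rose and 254 fell, 3.32% of the 17261 tested. Their changes were small, with medians of 1.19-fold and 1.20-fold, and 4 that rose and 13 that fell changed at least 2-fold. Genes at 10 to 100 CPM made up most of them, with 201 higher and 152 lower out of 6486. Under the rule for named genes, symbols aside, the 10 that led the rise had log2 fold changes of 0.56 to 0.91 and the 10 that led the fall -2.13 to -0.63. The lowest was ENSRNOG00000026415, at 7.62 ± 3.70 CPM with vehicle and 1.74 ± 0.51 CPM at 400 mg/kg (SD, n = 6; -2.13, SE 0.39, adjusted p = 0.0072). This gene followed the sequencing set: it was at 6.30 to 12.1 CPM in the 10 libraries of the first set, and at 1.56 and 2.34 CPM in the vehicle and 30 mg/kg libraries of the third. With the set as a term its log2 fold change was -0.04 (SE 0.29, adjusted p = 0.98). The adjusted p was 1.28e-05 to 0.0359 under RLE size factors, DESeq2, limma-voom and only the 12 libraries compared. With that term 1 gene was called in all, lower, and the term itself was called for 8 genes. DESeq2 called 1056 and limma-voom 1185, while 50 were called with a fold change of at least 1.5 and 242 without the vehicle libraries of conflicting labels, 2407 and 2408. The count fell to 159 without 400 mg/kg 2423, and lay between 256 and 361 without vehicle 2404, 2405, 2406 or 2408 or 400 mg/kg 2421 or 2426.

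At 150 mg/kg, 4 testis genes fell and 0 rose by edgeR (1080 at an unadjusted p under 0.05; DESeq2 called 7 higher and 9 lower, and limma-voom 1 lower). ENSRNOG00000026415 was among them, at 1.43 ± 0.337 CPM (SD, n = 6; -2.41, SE 0.39, adjusted p = 0.0257), and 0 genes were called with the set as a term (742 at an unadjusted p under 0.05). The 4 genes were also called lower at 400 mg/kg, where independent lists would share 0.0589. When each dose was set against a different 3 of the vehicle libraries, 0.9 and 101 genes were called on average and 0.2 were shared; here too both doses share their difference in set from vehicle. Leaving out 1 library gave 0 to 9 genes: 0 without vehicle 2407 or 150 mg/kg 2416, 2417 or 2420, 2 without vehicle 2403, 2404 or 2405 or 150 mg/kg 2419, and 9 without vehicle 2408. At 30 mg/kg, 1 testis gene rose, by 1.38 on the log2 scale (adjusted p = 0.0451), and 0 fell (1808 at an unadjusted p under 0.05; DESeq2 called 17 higher and 25 lower, and limma-voom 1 higher and 9 lower). It was not called when any 1 of the 12 libraries but 30 mg/kg 2410 or 2412 was left out; without 2412, 61 genes were called. It was not called with the set as a term, nor within the first set, where 1 other gene was. ENSRNOG00000026415 was at 8.69 ± 3.42 CPM there (0.19, SE 0.35, adjusted p = 0.893).

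Between 150 and 400 mg/kg in testis, 106 genes were higher and 28 lower at 400 mg/kg, with log2 fold changes up to 0.77 and down to -0.71 among the leading genes under the rule. ENSRNOG00000026415 differed by 0.28 (SE 0.42, adjusted p = 0.806). With only the 12 libraries compared, and also within the second set, 1 gene was called; 59 were called without a filter, 11 with a fold change of at least 1.5, 369 by DESeq2 and 218 by limma-voom. The count without 1 library was 0 to 4 for 150 mg/kg 2415 and 2418 and 400 mg/kg 2423, 2424 and 2426, 48 to 71 for 150 mg/kg 2417 and 2420 and 400 mg/kg 2421, and 210 to 246 for 150 mg/kg 2416 and 400 mg/kg 2422 and 2425.

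The effect of 400 mg/kg differed between the tissues for 1524 of 18221 genes, with a higher log2 fold change in liver for 964 and a lower one for 560. Of these genes, 1161 were called in liver alone or in both tissues, 115 in testis alone or in both, 37 in both and 285 in neither. A difference of at least 1 on the log2 scale was seen for 369 of them. ENSRNOG00000033680 was at 0.563 ± 0.146 CPM in testis with vehicle and 0.653 ± 0.174 at 400 mg/kg (SD, n = 6), and its effect was higher in liver by 8.82 (SE 0.74, adjusted p = 1.18e-11). ENSRNOG00000020775 had 0 to 2 reads in each testis library, too few for a fold change there. Its difference between the tissues was 6.89 (SE 4.5, adjusted p = 0.436 in the main edgeR fit). With a block on the title number the adjusted p was 0.027, so its call turned on the block. ENSRNOG00000026415 did not pass the test in liver, at 48.6 ± 4.82 CPM with vehicle and 49 ± 7.74 CPM at 400 mg/kg (SD, n = 6; 0.01, SE 0.087, adjusted p = 0.945). With the sequencing set as a term in each tissue, 479 genes were called, 206 higher in liver and 273 lower, and 383 of them were among the 1524.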

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

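The tests of the sequencing set against the 150 mg/kg counts, against the share of reads without a unique alignment and on a single gene, and the fits with the set as a term, were chosen only after those results were seen; the other tests were fixed before their results. Dixon's test was made 48 times, for a measure or a gene in a group of 6 libraries, so that each of the 8 groups was tested several times. In 13 of the 48 tests 1 library stood apart from the rest, where chance marks about 1 in 20. Of these, 7 were totals of gene reads, all in libraries of the third set. That set was defined by its depth in testis, so the testis totals are no separate finding. In testis, vehicle 2408 had 45.5, 150 mg/kg 2415 had 49.2 and 400 mg/kg 2421 had 43.1 M gene reads. In liver, vehicle 2408 had 49.1, 30 mg/kg 2414 had 47.4, 150 mg/kg 2415 had 46 and 400 mg/kg 2421 had 45 M. Liver 150 mg/kg 2419 had the lowest share of reads outside genes of its group, 4.6%, and liver 400 mg/kg 2426 the highest share in the 10 most abundant genes, 27.7%. In liver, ENSRNOG00000033680 was lowest in its group in 30 mg/kg 2414, at 22.5 CPM, still above every vehicle library, and ENSRNOG00000020775 was highest in 150 mg/kg 2416, at 863 CPM. ENSRNOG00000026415 in testis was lowest in vehicle 2408, at 1.56 CPM, and in 30 mg/kg 2414, at 2.34 CPM.

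The effect of 400 mg/kg differed between liver and testis, by the test of the difference, for 1524 genes. Splitting the 12 title numbers of the vehicle and 400 mg/kg groups in 50 ways, only the true split (1 of 50) called that many, and the highest other called 25. Chance is thus made unlikely, though not all exchanges of 1 title number were run. Among genes given by ID, the difference was 8.82 on the log2 scale for ENSRNOG00000033680, -6.62 for ENSRNOG00000030868 and 2.16 for ENSRNOG00000026415. ENSRNOG00000030868 had only 2 to 10 reads per testis library with vehicle and 5 to 18 at 400 mg/kg, and was not tested within testis. The difference for ENSRNOG00000026415 rests on the testis fall that follows the sequencing set: with the set as a term the testis fold change was -0.04 (SE 0.29, adjusted p = 0.98), beside 0.01 in liver.

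In testis, 573 genes were called at 400 mg/kg. Of 100 splits of the 12 libraries only the true one (1 of 100) called that many, with 31 in the highest other. Among all 36 exchanges of 1 vehicle and 1 400 mg/kg library, that of 2403 and 2422 called 259. Chance is thus made unlikely, though not excluded by the splits sampled. Against the set as the whole cause, 150 mg/kg, which has the same imbalance of sets, called 4 genes. These 2 counts do not test the difference between the doses. The direct test of 400 against 150 mg/kg called 134 genes, but 1 with only the 12 libraries compared and 1 within the second set. Exchanging vehicle 2408, the vehicle library outside the first set, with each 400 mg/kg library keeps the imbalance and called 0 to 11 genes, median 3, where the set alone would give about 573. The bound written before this test, a median no higher than the highest of the medians for the other 5 vehicle libraries, was not met (3 against 2), and the comparison with 573 was made after the values were seen. The set may still account for single genes, such as ENSRNOG00000026415, at 2.34 CPM or less outside the first set at the lower doses, within the 1.05 to 2.46 CPM of the 150 and 400 mg/kg libraries, and for how many more stays open: with the set as a term 1 gene was called, and a single vehicle library links the sets. That library, 2408, is 1 of the 2 with conflicting labels, so its exchanges and the set term hold only if it is vehicle. Liver 2407 and 2408 had ENSRNOG00000033680 at 3.52 and 5.73 CPM, and the lowest treated liver library had 22.5. They had ENSRNOG00000020775 at 36.6 and 57.9 CPM, and the lowest treated liver library had 92.3. If the title numbers mark animals, which the labels do not state, these values argue that both received vehicle.

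In liver, the same tests bear on the 2608 genes called at 400 mg/kg. Chance is made unlikely, since of 100 splits only the true one (1 of 100) called that many. The highest other, which exchanged 1 vehicle and 1 400 mg/kg library, called 773. Among all 36 such exchanges the highest called 818. The count of 198 at 150 mg/kg and a median of 31, range 0 to 312, over the 6 exchanges of vehicle 2408 (medians of 3 to 114 for the others) argue against the set as the whole cause. Part of the count remains open to it, since 936 genes were called with the set as a term, which also raised standard errors, as for ENSRNOG00000020775 from 0.34 to 0.57. The liver comparison of 400 with 150 mg/kg, balanced over the sets, called 664 genes. It called 711 with the set as a term of 2 levels and 68 within the second set. These values argue that liver expression differed with dose apart from the set. How many of the 2608 genes respond to the dose stays open.

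Reads without a unique alignment, which enter no gene count, took 25.9% ± 1.49 of liver reads with vehicle, 28.6% ± 0.908 at 150 mg/kg and 29.3% ± 1.24 at 400 mg/kg (SD, n = 6, exact permutation p = 0.00433 and 0.00216, adjusted 0.0208 and 0.0173 over 24 tests); 5 and 6 of the 6 libraries lay above every vehicle library. Liver 2408 and 2414 had 25.6% and 26.5%, below the 27.1% to 31.5% of the 12 libraries at 150 and 400 mg/kg. For this the exact permutation p was 0.011, the smallest possible (n = 2 and 12). The test cannot decide on the sequencing set, since of the 12 only 2415 and 2421 share the set of 2408 and 2414. Within that set, 150 mg/kg 2415 and 400 mg/kg 2421 had 29.25% and 29.24%, above vehicle 2408 and 30 mg/kg 2414. A difference between sets cannot give this gap within 1 set, though these libraries are too few for a test. Whether the set adds to the rise over all libraries stays open. Reads shared between near-identical genes stay open, as untested without gene names. In testis, the share of reads outside genes was 11.1% ± 0.106 with vehicle, 11.7% ± 0.392 at 30 mg/kg, 11.3% ± 0.204 at 150 mg/kg and 11.6% ± 0.208 at 400 mg/kg (SD, n = 6, exact permutation p = 0.0108, 0.121 and 0.00216, adjusted 0.0432, 0.288 and 0.0173), with 5, 3 and 6 of 6 libraries above every vehicle library. In liver the same share was lower, at 5.27% ± 0.249 with vehicle, 4.89% ± 0.151 at 150 mg/kg and 4.96% ± 0.0854 at 400 mg/kg (SD, n = 6, exact permutation p = 0.00433 and 0.013, adjusted 0.0208 and 0.0446). The 150 and 400 mg/kg groups are confounded with the set.

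The other counts were split in 100 ways each. Only the true split (1 of 100) called as many genes for liver at 150 mg/kg (198, highest other 82) and at 30 mg/kg (2, highest other 1). The same held for liver 400 against 150 mg/kg (664, highest other 43), testis at 150 mg/kg (4, highest other 2) and testis 400 against 150 mg/kg (134, highest other 97). Random regrouping thus seldom gives such counts, but not all exchanges of 1 library were run for them. In testis at 400 mg/kg those exchanges reached 259 genes, against 31 in the sampled splits. By these splits alone chance is therefore not excluded where margins are narrow, as for liver at 30 mg/kg and both testis counts. The 2 liver genes at 30 mg/kg had adjusted p of 2.00e-05 and 0.000479 by edgeR. Both stayed called in each of the 12 fits without 1 library. These values argue against chance for those 2 genes. The testis count of 134 was 1 with only the 12 libraries compared. The splits do not hold the sequencing sets fixed: for 150 and 400 mg/kg against vehicle and for the tissue difference, a single other split was as unequal in sets as the true one. It exchanged vehicle 2408 with 1 treated library, and for 150 mg/kg against vehicle it called 0 genes in liver, against 198, and 2 in testis, against 4. In liver, 107 genes were called at 150 mg/kg with the set as a term of 2 levels, 61 of them among the 198, and ENSRNOG00000033680 had a log2 fold change of 8.12 (adjusted p = 8.6e-06), so the set is not the whole cause there, and its part in the count stays open. In testis, 0 genes were called at 150 mg/kg with the set as a term, and the set stays open. For testis at 30 mg/kg, 7 of the 100 splits called 1 gene or more and the highest other called 21, so chance is not excluded.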

How the results depend on the processing

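The sequencing set alternatives were chosen after the data were examined; the cause of the changes was not tested unless the setting itself gives it. With RLE size factors no count moved by over 1.5 times. DESeq2 called 19, 494 and 1035 genes in liver at 30, at 150 and for 400 against 150 mg/kg, and 42, 16, 1056 and 369 in testis at 30, 150 and 400 and for 400 against 150 mg/kg; limma-voom called 4 in liver at 30 mg/kg and 10, 1, 1185 and 218 in testis. A fold change of at least 1.5, a stricter call by construction, left 85, 834 and 145 in liver at 150, at 400 and for 400 against 150 mg/kg, and 50 and 11 in testis at 400 and for 400 against 150 mg/kg. Without a filter, with more genes tested, 400 against 150 mg/kg gave 418 in liver and 59 in testis. With only the 12 libraries compared, fewer samples, it gave 288 and 1, and liver at 30 mg/kg gave 4. Testis at 30 mg/kg gave 0 with a mean CPM of at least 1, 2 with a fit that was not robust and 0 without the 2 libraries of conflicting labels, which left 242 at 400 mg/kg. With the set as a term of 2 levels, liver gave 107 at 150 and 936 at 400 mg/kg, testis 0 at 30, 0 at 150 and 1 at 400 mg/kg, and the tissue difference 479; with 3 levels, liver gave 209 at 150 and 695 at 400 mg/kg and testis 0, 0 and 0. Within the first set liver at 30 mg/kg gave 4; within the second, 400 against 150 mg/kg gave 68 in liver and 1 in testis. Leaving out 1 library in turn gave, in liver, 2 to 5, 104 to 242, 2065 to 2557 and 398 to 718 genes at 30, 150 and 400 and for 400 against 150 mg/kg, and in testis 0 to 61, 0 to 9, 159 to 809 and 0 to 246. The tissue difference stayed within 1.5 times under the other 5 alternatives, at 1240 to 1484. A replicate block on the title number gave 1240 genes, 1158 of them among the 1524. Deviations from group means over 6816 genes correlated at 0.047 to 0.31 for the 24 same-numbered pairs (median 0.17), over 0.1 for 21. For other pairs they correlated at -0.21 to 0.22 (median -0.0031). Of the 24 libraries of each tissue, 21 in liver and 19 in testis correlated best with their own number. These values argue that the numbers pair the samples, which the labels do not state. The main fit across tissues treated libraries of the same number as independent. The 12 fold changes given by ID had 59 alternative values, of which 53 kept the call and 6 lost it. These came from RLE size factors, DESeq2, limma-voom, only the 12 libraries compared and the set as a term of 2 levels. Fits without 1 library or the 2 of conflicting labels, within a set, with 3 set levels, another filter or not robust were not tallied. Some of them called 0 testis genes at 150 mg/kg, where the call for ENSRNOG00000026415 was therefore lost too. With the set as a term the fold change of ENSRNOG00000026415 in testis was lost, at -0.32 (SE 0.29, adjusted p = 1) at 150 and -0.04 (SE 0.29, adjusted p = 0.98) at 400 mg/kg. Its call at 150 mg/kg also ended with limma-voom (-2.12, adjusted p = 0.268) and with only the 12 libraries (-2.41, adjusted p = 0.245), in a range of 2.61e-06 to 1 over its alternatives. Alternatives for gene lists and symbols were not run, since no ID had a name. Depth limits genes at a few reads per library, such as ENSRNOG00000030868 at 400 mg/kg.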

Other observations

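The test of the tissue classes used genes grouped after the names were found missing; the predictions for these tests were written before their results. In liver at 400 mg/kg, 435 of 1287 genes at least 8-fold higher in liver than in testis were called, of which 286 fell and 149 rose. Of 10180 genes under 8-fold apart 1868 were called, and of 1808 at least 8-fold higher in testis 305. These shares were not tested against each other, and the share called also rose with expression level, from 10.2% under 1 CPM to 36.7% over 100 CPM. The median log2 fold change of these liver-enriched genes was -0.084 and 37.8% of them were positive. At 150 mg/kg the same class had 44 higher and 6 lower, with a median of 0.0039. At 400 mg/kg camera placed the class lower with the preset correlation of 0.01 (adjusted p = 0.0495 over 18 tests), and the call was lost with an estimated correlation (p = 0.242, adjusted p = 0.726). Genes under 8-fold apart were placed higher than the rest with an estimated correlation (adjusted p = 0.00152) and not with the preset one (adjusted p = 0.2), though their median was -0.0043 and their mean -0.018. In liver at 150 mg/kg, camera placed genes at least 8-fold higher in testis lower (median -0.063, adjusted p = 0.0256), a call lost with an estimated correlation (adjusted p = 0.104). The fry test, which sets the class against no change and not against other genes, gave an adjusted p of 0.0148. A joint fall of liver-enriched genes at 400 mg/kg is a hypothesis that these libraries leave open. In testis at 400 mg/kg, genes at least 8-fold higher in testis showed no joint shift: 89 rose and 80 fell of 3933, their median was -0.0019 and the camera p was 0.96, or 0.986 with an estimated correlation. At 150 mg/kg camera placed this class lower (median -0.027, 36.8% positive, adjusted p = 0.00414), a call lost with an estimated correlation (adjusted p = 0.686).

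A response shared by both tissues was tested as a hypothesis over the 12365 genes tested in both. Of these, 52 were called at 400 mg/kg in the same direction in both tissues, 27 higher and 25 lower, where independent lists would give 45.8, and 33 in opposite directions, where they would give 45.1. The excess is too small for the limit of 1.5 times set beforehand, and the test leaves the hypothesis open. The tissues also share title numbers and the imbalance of sequencing sets, which the values for independent lists do not take into account.

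Fold changes at 30 mg/kg followed those at 400 mg/kg in liver beyond what the shared vehicle libraries give. Across 13275 genes, which are not independent replicates, their correlation was 0.445, below the 0.464 to 0.535 of simulated unchanged groups, but their covariance was 0.0388 against a simulated mean of 0.0194. With the vehicle libraries divided between the doses, the covariance was 0.0164 to 0.0216, above 0 in each of 10 divisions, and the correlation 0.143 to 0.199. For 150 and 400 mg/kg the covariance was 0.0885, and 0.066 to 0.0712 with divided controls, which leave the sequencing set that both doses share. In testis the divided covariance of 30 and 400 mg/kg was 0.00461 to 0.0076, and that of 150 and 400 mg/kg, which share the set, 0.00273 to 0.00572. For 30 and 150 mg/kg it was 0.00747 to 0.0127 in liver and -0.000857 to 0.00213, on both sides of 0, in testis. The 10 divisions reuse the same treated libraries, so their ranges are not a sampling spread.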
